A study of Chlamydomonas reinhardtii with 9 samples.

How the data were processed

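Total RNA of the green alga Chlamydomonas reinhardtii was compared on 9 spotted arrays with 2 channels each. Per the labels, channel 1 of 3 arrays held RNA of the nonphotosynthetic mutant mcd1-1 and channel 2 held wild-type RNA (strain P17). Another 3 arrays set the mutant mcd1-2 against the same wild type, and the last 3 set the photosynthetic suppressor mcd2-1 against mcd1-2. The labels number the arrays of each comparison 1 to 3. No label says whether these came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

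The deposited table holds log ratios of the 2 channels for 213 spots, made by the authors. The scanner, image analysis, background correction, normalization and dyes are not given in the sources used here, nor are the spot intensities, so no signal floor could be set. The number of arrays limits the precision. The base of the logarithm is not given either. It was taken as 2 because the most extreme deposited value is -13.4, and a natural log ratio of intensities on a 16-bit scale cannot exceed 11.1 in size, while a log2 ratio can reach 16. A ratio made from intensities below 1 unit would leave the base open. Only 2 spots lie below -10, at -13.4 and -11.63. The other spots of their probes on that array were at -0.53 and -0.49, and at 0.74 and 0.88. The base, and with it every fold change, therefore rests on 2 single spots that may be defective. The direction is not given. It is taken here as channel 1 over channel 2 (mutant over wild type, suppressor over mutant), the order of the labels. The labels call the strains petD mutants, and the largest change in the table was negative on all 6 mutant arrays and positive on all 3 suppressor arrays. This direction is likely, not certain. If the ratios ran the other way, every higher would read lower and the totals of calls would not change. For the suppressor arrays the direction is not settled, because replicates 1 and 2 correlated at -0.314 across all probes, so the means of the suppressor probes named in the text are given with the sign of replicate 1 turned as well. Whether the deposited ratios had been centred is not given.

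Spots were grouped in consecutive sets of 3, giving 71 probes. The annotation given with the series names 33 spots, which form 11 such sets. The median SD over 3 spots was 0.1001 with this grouping, and 0.318 and 0.321 when the grouping was shifted by 1 or 2 spots. All 11 named probes carry 1 nuclear locus tag each, and all 11 loci matched the RefSeq table of assembly Chlamydomonas_reinhardtii_v5.5. The other 60 probes (180 spots) are unnamed here and are given by spot number. No probe could be tied to petD, to MCD1 or to any chloroplast gene, so the results fixed in advance for petD and for the lists of chloroplast genes are not reported. Only the list of nuclear genes could be tested. Functions of the nuclear loci are given as general background and are not in the tables. No coordinates are given because the files name no genome build.

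The deposited values, taken as log2, were averaged over the 3 spots of a probe. The plan, fixed before the data were examined, was to use the values as deposited if every array median lay within 0.3 of 0 and otherwise to subtract each array's median. The medians of 2 arrays lay beyond 0.3, so each array's median over probes was subtracted. In the order of the replicate numbers, the deposited spot medians were -0.11, 0.01 and -0.22 for mcd1-1, 0.08, 0.40 and -0.12 for mcd1-2, and 0.07, 0.46 and -0.06 for the suppressor. A probe needed values on at least 2 arrays of each group, which all 71 met. One linear model with a mean per group was fitted over all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual degrees of freedom, prior SD 0.692 with 14.6 prior degrees of freedom). Each group mean was tested against 0. The difference between mcd1-2 and mcd1-1, and the sum of mcd1-2 over wild type and suppressor over mcd1-2 (an indirect ratio of suppressor over wild type), were tested as contrasts. These limma tests were two-sided with Benjamini-Hochberg adjustment over 71 probes and a threshold of 0.05. With 3 arrays, an exact sign-flip test cannot go below 0.25, and a test of 3 arrays against 3 cannot go below 0.1, so the limma p-values rest on the model. The list of 11 nuclear loci was tested with camera at a preset correlation of 0.01 over the 66 probes with a value on all 9 arrays.

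The probes named were those past the threshold with one sign on all arrays of the comparison (for the difference, no overlap between groups), at most 10 in each direction. Where fewer than 10 passed, the 5 highest and 5 lowest means were added as values, summarised as ranges with examples. The nuclear locus with the largest change was also named, and the other nuclear loci are given because they are the only named probes. Intervals are 95% intervals of the moderated fit. That fit gives all groups one spread per probe, so its intervals and p-values pool unequal spreads. The median SD between arrays was 0.3495 for mcd1-1, 0.4435 for mcd1-2 and 0.848 for the suppressor. Going by these medians, intervals may be too wide for mcd1-1 and too narrow for the suppressor. Single probes can differ: spots 97 to 99 had an SD of 1.35 in mcd1-1 and 0.56 in mcd1-2. Their mcd1-1 interval may therefore be too narrow. In 100 datasets simulated for the comparison of mcd1-1 with wild type, 6 of 71 probes were changed. The procedure found 19% of changes of 1 on the log2 scale, 86.5% of changes of 2 and 100% of changes of 4. Of its calls, 5.52% were false. The simulated probes were normal and independent, with one spread per probe on all 9 arrays. The real arrays differed in spread between groups and neighbouring probes correlated, so these rates may not hold for them.

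The alternatives planned before the data were examined were no centring, scaling arrays to one spread (normalizeMedianAbsValues in limma), a fit of only the groups compared, the replicate number as a block, only probes complete on 9 arrays, no filter, the median of the 3 spots, robust moderation, array weights, and leaving out each array. The alternatives that named petD could not be run. Those chosen after seeing the data were a block for 3 arrays that share missing probes, subtraction of the median of 11 neighbouring probes, removal of 2 spots below -10, turning the sign of suppressor replicate 1, and correlations without spots 97 to 99.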

Results

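The arrays measured relative RNA levels in 3 comparisons of 3 arrays each: mcd1-1 over wild type, mcd1-2 over wild type, and the suppressor mcd2-1 over mcd1-2. Values are log ratios, taken as log2, after subtraction of each array's median, in the likely direction of channel 1 over channel 2. Fold changes rest on that base. A probe is the set of 3 consecutive spots that carry its numbers. Each array gave values on 197 to 213 of the 213 spots. The 3 spots of a probe had a median SD per array between 0.0325 and 0.205. Arrays of one group differed more than spots did. The median SD between arrays was 0.3495 for mcd1-1, 0.4435 for mcd1-2 and 0.848 for the suppressor. Correlation between arrays across all probes ranged from 0.541 to 0.898 for mcd1-1 and from 0.552 to 0.725 for mcd1-2. For the suppressor it ranged from -0.314 to 0.125, with the lowest value between replicates 1 and 2, so the direction of these arrays is not settled. Without the probe of spots 97 to 99 these ranges were 0.179 to 0.755, 0.347 to 0.602 and -0.364 to 0.0437 (across probes, which are not independent replicates). On mcd1-1 replicate 2, mcd1-2 replicate 3 and suppressor replicate 3 the same 4 probes had no value on any spot. For probes past the threshold, values are also given within this set of 3 arrays.

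The first comparison asked which RNAs differed in the nonphotosynthetic mutant mcd1-1. One probe fell: spots 97 to 99, unnamed in the annotation, had a log2 ratio of -5.34 ± 1.35 (SD, n = 3), 40.5-fold lower than in the wild type with a 95% interval from 21.1-fold to 78.0-fold. It was lower on 3 of 3 arrays, at -3.93, -5.49 and -6.60, and its adjusted p from limma was 9.48e-09. Its SD of 1.35 here was larger than in mcd1-2 (0.56) or the suppressor (0.86). The fit pools these spreads, so the interval and p-value for mcd1-1 may be too narrow and too small. No other probe passed the threshold. The highest were the unnamed probes of spots 205 to 207, at 1.39 ± 0.60 (SD, n = 3, limma adjusted p = 0.0643), and spots 178 to 180, at 1.19 ± 0.45 (SD, n = 3, limma adjusted p = 0.12). Both were above 0 on 3 of 3 arrays, and 32 of 71 probes had one sign on every array with a value. The lowest after spots 97 to 99 was spots 145 to 147, at -0.92 ± 0.32 (SD, n = 3, limma adjusted p = 0.44), which passed with array weights (-0.88, limma adjusted p = 0.0279, up to 0.988 over its alternatives). The 5 highest means lay between 0.79 and 1.39, and the 5 lowest between -5.34 and -0.65. At an unadjusted p under 0.05, 6 of 71 probes passed. For 20 of 71 probes the 95% interval lay within 1 of 0 on the log2 scale, and for 68 within 2. With the spread pooled over all groups, a change of 1 on the log2 scale was thus neither detected nor excluded for most probes. With array weights in the fit, 10 probes passed, 6 higher and 4 lower, among them spots 205 to 207 (1.24, limma adjusted p = 0.00186, between 0.00186 and 0.505 over its alternatives) and spots 178 to 180 (1.32, limma adjusted p = 0.000815, between 0.000815 and 0.988). Both also passed with arrays scaled to one spread (0.00566 and 0.0137). Spots 205 to 207 passed with robust moderation (0.0478) and without the spots below -10 (0.0326), and spots 178 to 180 with the median of neighbouring probes subtracted (0.0014). The fall of spots 97 to 99 was -5.49 on the array that shares missing probes and -5.27 on the mean of the other 2.

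In mcd1-2, the same question gave 4 probes past the threshold, 2 lower and 2 higher. Spots 97 to 99 were at -4.79 ± 0.56 (SD, n = 3), 27.7-fold lower than in the wild type with an interval from 14.4-fold to 53.2-fold (limma adjusted p = 6.58e-08). Spots 13 to 15 were at -3.16 ± 0.53 (SD, n = 3), 8.95-fold lower with an interval from 4.82-fold to 16.6-fold (limma adjusted p = 1.16e-05). Each fell on 3 of 3 arrays, and 28 of 71 probes had one sign on every array with a value. Spots 55 to 57 rose to 1.69 ± 0.62 (SD, n = 3), 3.24-fold (limma adjusted p = 0.013). Spots 58 to 60 rose to 1.68 ± 0.25 (SD, n = 3), with a 95% interval from 1.85-fold to 5.51-fold (limma adjusted p = 0.00564). All 4 probes are unnamed in the annotation. Below the threshold, the highest were spots 34 to 36 at 1.36 ± 1.53, above 0 on 2 of 3 arrays, spots 43 to 45 at 1.28 ± 0.79 and spots 46 to 48 at 1.25 ± 1.03 (SD, n = 3), with limma adjusted p of 0.122, 0.0601 and 0.152. Without mcd1-2 replicate 3, spots 34 to 36 passed at 2.23 (limma adjusted p = 0.00853, between 0.00853 and 0.981 over its alternatives), and it also passed with scaled arrays (0.0379), array weights (0.0114) and without the spots below -10 (0.0368). Spots 43 to 45 passed with scaled arrays (0.0215), the median of the 3 spots (0.0437), robust moderation (0.0461), array weights (0.0145) and without the spots below -10 (0.0327), with a limma adjusted p of up to 0.697 over the alternatives. Spots 46 to 48 passed with array weights (0.0326, up to 0.837 over the alternatives). The lowest below the threshold was spots 88 to 90 at -0.90 ± 0.71 (SD, n = 3, limma adjusted p = 0.216), which passed with array weights (-1.01, limma adjusted p = 0.0343, up to 0.981 over its alternatives). Both rises lost their call without mcd1-2 replicate 1 and without replicate 2. There only the 2 falls passed, and spots 55 to 57 stood at 1.58 and 1.45 (limma adjusted p = 0.124 and 0.227) and spots 58 to 60 at 1.70 and 1.54 (0.0519 and 0.116). Spots 55 to 57 also lost it with only the mcd1-2 arrays in the fit (1.69, limma adjusted p = 0.0637) and with the median of neighbouring probes subtracted (1.18, 0.109). The 5 lowest means lay between -4.79 and -0.71. With array weights 8 probes passed, and 8 had an unadjusted p under 0.05. Within the array that shares missing probes the ratios were -5.12, -3.75, 0.99 and 1.45 for spots 97 to 99, 13 to 15, 55 to 57 and 58 to 60, and in the other 2 arrays the means were -4.63, -2.87, 2.04 and 1.79.

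**Figure D1:**
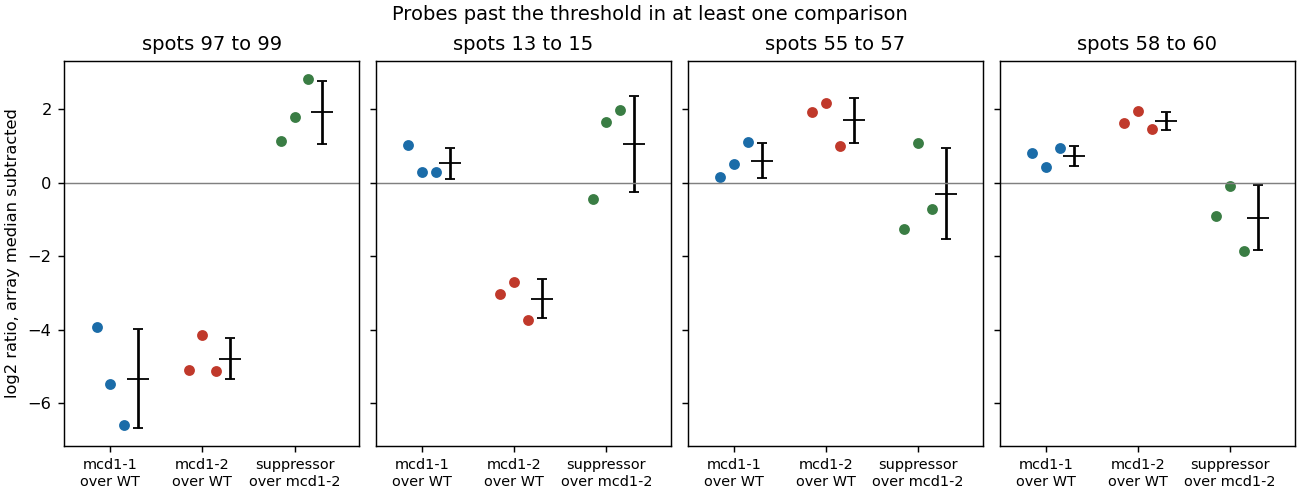
Log2 ratio after median subtraction (vertical axis) of the 4 probes that passed the threshold in at least 1 comparison, for the 3 groups of arrays (horizontal axis, likely direction); points are arrays and black bars the mean and SD of 3 arrays. Spots 97 to 99 lie between -6.60 and -3.93 on the 6 mutant arrays and between 1.13 and 2.83 on the 3 suppressor arrays, and spots 13 to 15 lie between -3.75 and -2.71 on the mcd1-2 arrays.

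The 2 mutants were then set against each other, both being measured against wild type. Spots 13 to 15 differed: the mean was 0.53 ± 0.42 in mcd1-1 and -3.16 ± 0.53 in mcd1-2 (SD, n = 3 each). The difference, mcd1-2 minus mcd1-1, was -3.69 (95% interval from -4.95 to -2.43, limma adjusted p = 0.000366). No array of one group overlapped the other, which held for 13 of 71 probes (chance gives this for 10% of probes). For spots 13 to 15 the values within the sets of arrays are given next. It was -4.03 between the arrays that share missing probes and -3.52 among the others. No other probe passed, and 2 probes had an unadjusted p under 0.05. The second was spots 46 to 48, at -0.48 in mcd1-1 and 1.25 in mcd1-2, a difference of 1.73 (limma adjusted p = 0.597). The 5 highest differences lay between 0.905 and 1.73, and the 5 lowest between -3.69 and -0.79. For spots 97 to 99 the mutants differed by 0.55, with an interval from -0.78 to 1.89, which leaves a difference of up to 3.70-fold open. The rises of spots 55 to 57 and 58 to 60 did not differ between the mutants past the threshold (differences of 1.09 and 0.95, limma adjusted p = 0.861 for both). One probe, spots 97 to 99, was past the threshold in both mutants, where independent lists of these lengths would share 0.0563, a value that leaves out the shared wild type. Across the 71 probe means the mutants correlated with Pearson's r of 0.635 and Spearman's rho of 0.384. Without spots 97 to 99 the values were 0.235 and 0.357. Without spots 13 to 15 as well, Pearson's r was 0.381, so its size depended on these 2 probes. The covariance was 0.4415 over all probes and 0.0744 without spots 97 to 99 alone. Part of this overlap and of any correlation may come from shared wild-type RNA, whose share could not be simulated from ratios alone. By the order of the labels both mutants were in channel 1. A lasting difference between the channels would also be shared, and cannot be told apart here.

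**Figure D2:**
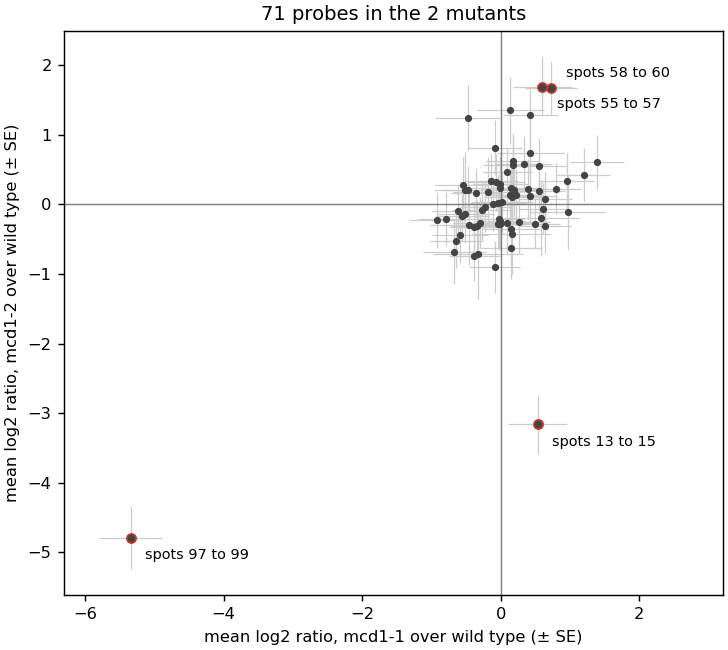
Mean log2 ratio of each of the 71 probes in mcd1-1 over wild type (horizontal axis) against mcd1-2 over wild type (vertical axis), in the likely direction, with SE from the fit; the 4 probes past the threshold in a comparison are labelled. Spots 97 to 99 lie at -5.34 and -4.79, and spots 13 to 15 at 0.53 and -3.16.

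The third comparison asked what differed in the photosynthetic suppressor relative to the mutant mcd1-2. The probe of spots 97 to 99 rose to 1.92 ± 0.86 (SD, n = 3), 3.77-fold with an interval from 1.96-fold to 7.26-fold (limma adjusted p = 0.0282). It was above 0 on 3 of 3 arrays, at 1.13, 1.78 and 2.83, and 14 of 71 probes had one sign on every array with a value. The probe of spots 97 to 99 was the only one past the threshold, and 6 of 71 had an unadjusted p under 0.05. With the sign of replicate 1 turned, it stood at 1.16 (limma adjusted p = 0.267). There 3 other probes passed: spots 13 to 15 at 1.35 and CHLRE_12g550850v5 at -1.68 (limma adjusted p = 0.0461 for both), and spots 160 to 162 at 1.77 (0.0387). The value of CHLRE_12g550850v5 includes a single spot at -11.63 on replicate 3. The call of spots 97 to 99 was also lost with only the suppressor arrays in the fit (1.92, limma adjusted p = 0.116), without suppressor replicate 2 (1.98, 0.0605), without replicate 3 (1.46, 0.364), with arrays scaled to one spread (1.57, 0.187), with array weights (2.13, 0.11) and with the median of neighbouring probes subtracted (1.85, 0.344). Over its alternatives the limma adjusted p ranged from 0.00291 to 0.364. The block for arrays that share missing probes gave 1.95 with a limma adjusted p of 0.0869. Within that array the value was 2.83, and the other 2 arrays averaged 1.46. Spots 13 to 15, low in mcd1-2, stood at 1.06 ± 1.31 (SD, n = 3, limma adjusted p = 0.389), above 0 on 2 of 3 arrays. Without suppressor replicate 1 that probe reached 1.81 with a limma adjusted p of 0.0194, and spots 28 to 30 passed as well, at -1.44 (limma adjusted p = 0.0392). Spots 58 to 60 stood at -0.95 ± 0.88 and spots 190 to 192 at -1.02 ± 0.20 (SD, n = 3, limma adjusted p = 0.389 for both), each below 0 on 3 of 3 arrays. They stood at -0.35 and -0.23 with the sign of replicate 1 turned, each below 0 on 2 of 3 arrays. Spots 55 to 57 stood at -0.30 ± 1.24 (SD, n = 3), and at 0.54 with that sign turned. Spots 28 to 30 stood at -0.81, and at -1.11 with the sign turned (limma adjusted p = 0.0595). The 5 highest means lay between 0.64 and 1.92, and the 5 lowest between -1.38 and -0.81. Among them, spots 127 to 129 stood at -1.23 and spots 175 to 177 at 0.98 (n = 2, limma adjusted p = 0.526 for both). With the sign turned they stood at 0.60 and -0.80.

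An indirect ratio of suppressor over wild type, the sum of mcd1-2 over wild type and suppressor over mcd1-2, set the suppressor against the wild type. Spots 97 to 99 were lower, at -2.87 (95% interval from -4.21 to -1.54, limma adjusted p = 0.0153), against -4.79 in mcd1-2. This was 7.33-fold below the wild type, with an interval from 2.90-fold to 18.5-fold. No other probe passed, and 5 had an unadjusted p under 0.05. Spots 13 to 15 stood at -2.10 (interval from -3.36 to -0.84, limma adjusted p = 0.083). That probe passed with arrays scaled to one spread (-2.39, limma adjusted p = 0.00742), without the spots below -10 (0.025), without suppressor replicate 2 (0.0297) and without suppressor replicate 3 (0.0185), with a range from 0.00742 to 0.44 over its alternatives. It stood at -1.81 (0.0601) with the sign of suppressor replicate 1 turned. Spots 55 to 57 stood at 1.39 (interval from 0.13 to 2.65, limma adjusted p = 0.48). The 5 highest means lay between 0.86 and 1.39, and the 5 lowest between -2.87 and -1.165. Among the lowest, spots 88 to 90 stood at -1.245 (limma adjusted p = 0.48), and at -0.80 with the sign of suppressor replicate 1 turned. The call for spots 97 to 99 was lost without centring (-2.58, limma adjusted p = 0.0916), with array weights (-2.64, 0.0946), with the median of neighbouring probes subtracted (-2.70, 0.142) and without mcd1-2 replicate 1 (-2.71, 0.103), mcd1-2 replicate 3 (-2.71, 0.135) or suppressor replicate 1 (-2.48, 0.103), with a range of the adjusted p from 0.00108 to 0.142 over its alternatives. With the sign of suppressor replicate 1 turned, spots 97 to 99 stood at -3.63 (limma adjusted p = 0.0441), and spots 55 to 57 passed as well, at 2.24. The block for arrays that share missing probes gave -2.80 for spots 97 to 99 (limma adjusted p = 0.0906), with -2.28 within that set and -3.17 outside it. Across probes, mcd1-2 over wild type and suppressor over mcd1-2 correlated at -0.4895, at -0.295 without spots 97 to 99, and at -0.228 with the sign of suppressor replicate 1 turned. The mcd1-2 RNA is the numerator of one ratio and the denominator of the other, so part of this value may come from shared RNA.

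The 11 probes with a gene name are nuclear loci, and none passed the threshold in any of the 5 comparisons, whether adjusted over all probes or adjusted over the list alone. With the sign of suppressor replicate 1 turned, CHLRE_12g550850v5 passed in the suppressor comparison (-1.68, limma adjusted p = 0.0461), a value that includes a single spot at -11.63. With array weights CHLRE_06g259900v5 passed in mcd1-1 (-0.73, limma adjusted p = 0.0454). In the indirect ratio CHLRE_03g182551v5 passed without suppressor replicate 2 (-2.998, limma adjusted p = 0.0381), a value that includes a single spot at -13.4. With all arrays it stood at -2.09, and at -0.66 without the spots below -10 (limma adjusted p = 0.754). In mcd1-1 all 11 means lay below 0, from -0.65 to -0.01, with a median of -0.14 against 0.14 for the unnamed probes. On single arrays 3, 9 and 10 of 11 lay below 0, in the order of the replicate numbers. The means below 0 were also 11 without centring, but 7 with the median of neighbouring probes subtracted, 8 without mcd1-1 replicate 2 and 6 without replicate 3. For the list as a whole the camera p was 0.192, and p = 0.513 with an estimated correlation of 0.348. In mcd1-2, 7 of 11 lay below 0 (camera p = 0.259, p = 0.571 with an estimated correlation). In the suppressor, 7 of 11 lay below 0 (camera p = 0.48, p = 0.721 with an estimated correlation), and 7 of 11 did so in the indirect ratio (p = 0.137, and p = 0.458 with an estimated correlation). With the sign of suppressor replicate 1 turned the camera p was 0.632 in the suppressor and 0.64 in the indirect ratio, and p = 0.822 and p = 0.825 with an estimated correlation. Without centring, 4 of 11 lay below 0 in the suppressor comparison and 4 of 11 in the indirect ratio, so the more frequent sign there changed with the centring. It was 5 of 11 in the suppressor comparison and 6 of 11 in the indirect ratio both with the sign of suppressor replicate 1 turned and without the spots below -10. Leaving out single suppressor arrays gave 4 to 10 of 11 below 0 in the suppressor comparison and 4 to 11 of 11 in the indirect ratio, the highest in each without replicate 2 and the lowest without replicate 3. For the difference between the mutants camera gave 0.982 and, with an estimated correlation, 0.991; there the mean was 0.0018 and the median 0.07, while camera's direction was lower. After adjustment over the 5 comparisons the lowest camera p was 0.432.

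Among the loci of the chloroplast ATP synthase, CHLRE_06g259900v5, which encodes the gamma subunit, stood at -0.65 ± 0.29 in mcd1-1, -0.53 ± 0.22 in mcd1-2 and 0.50 ± 0.95 in the suppressor (SD, n = 3). It was below 0 on 3 of 3 arrays of each mutant, the largest nuclear change in mcd1-1 (limma adjusted p = 0.581). One sign on every array with a value was held by 32 of 71 probes in mcd1-1 and 28 of 71 in mcd1-2. The delta subunit locus CHLRE_11g467569v5 stood at -0.31 ± 0.77, -0.26 ± 0.36 and 0.15 ± 0.42. Of the photosystem I loci in mcd1-1, CHLRE_05g238332v5, for the PsaD subunit, stood at -0.01 ± 0.30, and CHLRE_09g412100v5, for the PsaF subunit, at -0.04 ± 0.29. In mcd1-2 they stood at -0.23 ± 0.85 and 0.02 ± 0.98, and in the suppressor at -0.74 ± 0.39 and -0.12 ± 0.72. The photosystem II locus CHLRE_09g396213v5, for the PsbO protein of the oxygen-evolving complex, stood at -0.12 ± 0.31, 0.01 ± 0.10 and 0.30 ± 1.03. The loci of mitochondrial alternative oxidases, CHLRE_09g395950v5 and CHLRE_03g169550v5, stood at -0.01 ± 1.00 and -0.14 ± 0.72 in mcd1-1, at 0.24 ± 0.54 and 0.33 ± 0.37 in mcd1-2, and at -0.23 ± 0.70 and -0.13 ± 0.71 in the suppressor. CHLRE_07g326150v5 had the largest nuclear change in mcd1-2, at -0.74 ± 0.56 (limma adjusted p = 0.389). It stood at -0.38 ± 0.51 in mcd1-1 and -0.10 ± 0.09 in the suppressor. CHLRE_16g671400v5 stood at -0.02 ± 0.55, -0.28 ± 0.12 and 0.29 ± 0.67. Turning the sign of suppressor replicate 1 gave suppressor means of 0.90 for CHLRE_06g259900v5, 0.14 for CHLRE_11g467569v5, -0.12 for CHLRE_05g238332v5, -0.34 for CHLRE_09g412100v5 and 0.77 for CHLRE_09g396213v5. They were 0.31 for CHLRE_09g395950v5, 0.42 for CHLRE_03g169550v5, -0.09 for CHLRE_07g326150v5, 0.48 for CHLRE_16g671400v5 and -1.49 for CHLRE_03g182551v5.

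Suppressor values of 2 further loci were set by single spots of suppressor replicate 3. CHLRE_03g182551v5, the plastocyanin locus, stood at -0.33 ± 0.31 in mcd1-1 and -0.71 ± 1.01 in mcd1-2, and its suppressor mean was -1.38 ± 2.91 (SD, n = 3). One of its 3 spots there was at -13.4 while the other two were at -0.53 and -0.49, and without that spot the suppressor mean was 0.05. CHLRE_12g550850v5, for the PsbP protein of photosystem II, stood at -0.45 ± 0.35 and -0.30 ± 0.19 in the mutants, and at -0.52 ± 2.54 in the suppressor. One spot was at -11.63 beside 0.74 and 0.88, and without it the suppressor mean was 0.86 (limma adjusted p = 0.374). Over all alternatives for this probe the limma adjusted p ranged from 0.0461 to 0.963. The lowest belonged to a mean of -1.68, with the sign of suppressor replicate 1 turned and that spot kept.

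**Figure D3:**
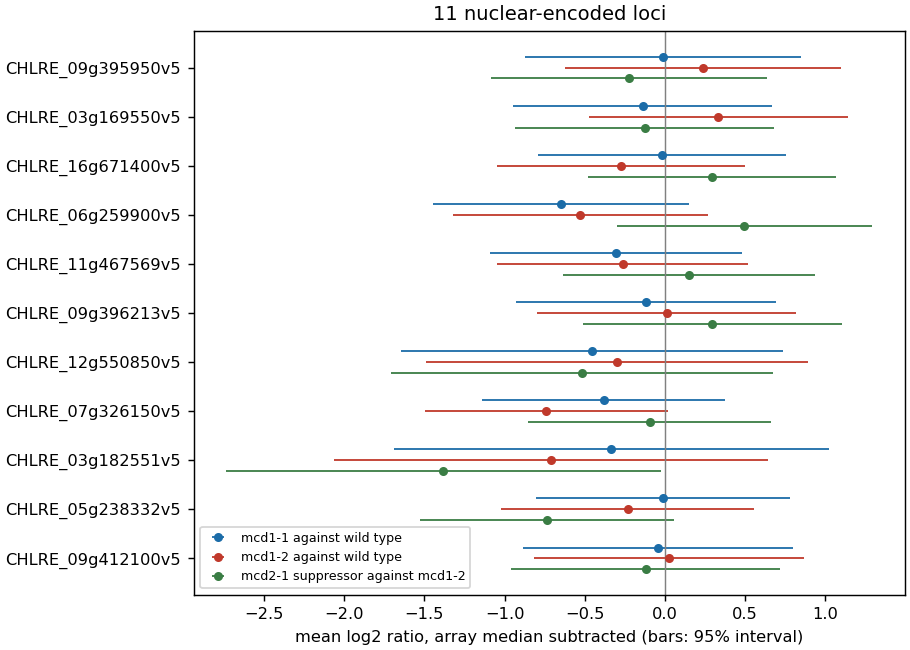
Mean log2 ratio after median subtraction (horizontal axis, with 95% intervals) of the 11 nuclear loci (vertical axis) in the 3 comparisons, in the likely direction. No locus passed the threshold, and the suppressor value of CHLRE_03g182551v5, at -1.38, includes a single spot at -13.4.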

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

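The tests of explanations in this part were chosen after the result was seen, except the count over splits of the arrays, which was planned. Spots 13 to 15 are given here because their response differed between the mutants by a test of the difference itself: mcd1-2 minus mcd1-1 was -3.69, with means of 0.53 in mcd1-1 and -3.16 in mcd1-2. In the sets of arrays formed by shared missing probes, the difference was -3.52 where it was nearest to 0. One set holds 1 array of each mutant and the other holds 2, so these sets could not create a difference between the mutants. No label says whether the arrays of the 2 mutants were printed or processed apart. Such an effect cannot be told apart from the mutants here. A single defective spot is excluded, because the SD over the 3 spots was at most 0.1854 on these 6 arrays. A lasting difference of the mcd1-2 strain that the suppressor kept may account for it, and this stays open: it would leave suppressor over mcd1-2 near 0, and the mean there was 1.06 with an interval from 0.17 to 1.95 over arrays that disagreed, and 1.35 with the sign of suppressor replicate 1 turned. The labels' own difference, another allele in another strain, is untested, and the probe's gene is not named here.

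None of the other 9 splits of the 6 mutant arrays into 3 and 3 gave a call for the difference, against 1 in the real split, which is 1 of 10. These splits are too few for a share under 0.05.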

How the results depend on the processing

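Spots 97 to 99 stayed past the threshold in both mutants, and spots 13 to 15 in mcd1-2 and in the difference between mutants, under every alternative run for them. The size of the limma adjusted p varied widely, however. For spots 97 to 99 it reached 0.00374 in mcd1-1 and 0.00225 in mcd1-2. For spots 13 to 15 it reached 0.00616 in mcd1-2 and 0.011 in the difference. The count for that difference was 1 throughout. In mcd1-1 the count of 1 became 3 with arrays scaled to one spread, 2 with robust moderation, 10 with array weights, 2 with the median of neighbours subtracted and 2 without spots below -10. In mcd1-2 the count of 4 became 8 with array weights, 6 with scaled arrays, 6 without spots below -10, 5 with the median of the 3 spots, 5 with robust moderation, 3 with neighbours subtracted and 3 with only that group fitted, and leaving out single arrays gave 2 to 5. For the suppressor over mcd1-2 the count of 1 became 0 with scaled arrays, array weights, the fit of that group alone, the block for shared missing probes or neighbours subtracted. It became 3 with the sign of suppressor replicate 1 turned, none of them spots 97 to 99, and leaving out single arrays gave 0 to 3. For the indirect ratio the count of 1 became 0 without centring, with array weights, with the block for shared missing probes or with neighbours subtracted. It became 2 with scaled arrays, 2 without spots below -10 and 2 with the turned sign, and leaving out single arrays gave 0 to 3. The correlation between the mutants fell from 0.635 to 0.235 without spots 97 to 99, and that of mcd1-1 with the suppressor ratio went from -0.355 to -0.00678, and to -0.132 with the turned sign over all probes. For these changes the cause was not tested, except for the correlations and for calls gained in the mutants without spots below -10. The correlations without spots 97 to 99 changed through the probe left out, and the value of -0.132 through the sign turned. The gained calls kept their ratios, at 1.39 for spots 205 to 207, 1.36 for spots 34 to 36 and 1.28 for spots 43 to 45. The removed spots lay in other probes, on suppressor replicate 3, so these calls came through the fitted spread and not through the ratios. As a replicate block, the array numbers gave counts of 1 for mcd1-1, 4 for mcd1-2, 1 for the suppressor, 1 for the difference between mutants and 3 for the indirect ratio, where spots 13 to 15 and CHLRE_03g182551v5 were added. Same-numbered arrays did not all deviate together (correlations of deviations between -0.3753 and 0.3787, the highest for replicate 2 of mcd1-2 and of the suppressor), so the numbers were not taken as pairs. The best correlate in another group had the same number for 2 of 9 arrays. The medians of the mcd1-2 and suppressor arrays lay close by number (0.08, 0.40 and -0.12 against 0.07, 0.46 and -0.06), and replicate 3 of both lacked 5 probes, so a link by number between these groups is not excluded. The alternatives for petD and without petD were not run, since no probe is tied to petD. Dropping the filter on missing values changed nothing, since all 71 probes met it. Signal over background is not known here, so ratios of the strongest falls have no stated floor.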

Other observations

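The tests of identity and of neighbouring probes in this part were chosen after the values were seen; the counts over sign patterns were planned. The labels describe petD mutants, petD being the chloroplast gene of subunit IV of the cytochrome b6f complex, but the tables tie no probe to it. One hypothesis is that spots 97 to 99 may be a petD probe. The profile such a probe would need, below -1 on all 6 mutant arrays and above 0 on all 3 suppressor arrays, was held by 1 probe of 71, spots 97 to 99. The profile was chosen after this probe was seen. With the sign of suppressor replicate 1 turned, this probe was at -1.13 on that array and 0 probes held the profile. The part on the mutants alone, below -1 on all 6 arrays, was held by 1 probe. Its mean over the 6 mutant arrays was -5.06, and the lowest of any other probe was -1.32. The hypothesis stays open, since the suppressor direction is not settled, another RNA lost in both mutants would look alike, and the direction of the ratios was judged partly from this probe.

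The 5 highest probes in mcd1-2 had nearby spot numbers: spots 34 to 36 (1.36), 43 to 45 (1.28), 46 to 48 (1.25), 55 to 57 (1.69) and 58 to 60 (1.68), with values between -0.11 and 0.46 for the 4 probes among them. Mean ratios of neighbouring probes correlated in mcd1-2 (lag-1 autocorrelation 0.255, permutation p = 0.0045) and in mcd1-1 (0.265, p = 0.0079), and had a value of -0.068 for the suppressor (p = 0.676) that became 0.292 (p = 0.0033) with the sign of replicate 1 turned, each without spots 97 to 99. Defective spots do not explain it, as the SD over the 3 spots of these 5 probes was at most 0.1883 on any mcd1-2 array. Position on the slide could: the deviations of single arrays from their group mean, which hold no group effect, also correlated between neighbours, with a mean of 0.238 and values above 0 on 9 of 9 arrays (permutation p = 1e-04, the smallest 10000 permutations can give). With that sign turned the mean was 0.19, above 0 on 8 of 9 arrays. The prediction written for these deviations asked only for a mean above 0. Spot numbers may equally follow gene groups whose RNAs vary together, which is untested because the probes are unnamed. After the median of 11 neighbours was subtracted, spots 58 to 60 stood at 1.13 (limma adjusted p = 0.0327) and spots 55 to 57 at 1.18 (limma adjusted p = 0.109). Spots 43 to 45 went to 0.77, spots 46 to 48 to 0.52, and spots 34 to 36 stayed at 1.36 (limma adjusted p of 0.149, 0.532 and 0.308).

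Turning the signs of single arrays gave a count of how often other patterns reached as many probes. For mcd1-1 the real pattern alone, 1 of 4, gave its 1 probe, with 0 as the highest of the others. For mcd1-2 the real pattern alone, 1 of 4, gave its 4 probes, again with 0 as the highest other. For the suppressor 2 of 4 patterns gave at least its 1 probe, and the highest other gave 3. These 4 patterns are too few for a share under 0.05. For the indirect ratio 8 of 32 patterns gave at least its 1 probe, the highest other giving 6. Patterns that turn only suppressor arrays keep the mcd1-2 ratio of spots 97 to 99, at -4.79, in the sum. They therefore still hold an effect, so this count can neither exclude chance nor point to it.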
